A study of Eucommia ulmoides with 102 samples.

How the data were processed

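Total RNA of 102 Eucommia ulmoides samples was hybridised to a custom one-colour array, 1 array per sample. Per the labels' protocols, the trees were wild individuals planted at one site in Japan, RNA was extracted with an RNeasy Plant Mini kit and treated with DNase, and Cy3-labelled cRNA was made with Agilent's One-Color Low RNA Input kit. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.5.3. The per-array files hold, per the file headers, a processed signal per spot, an intensity that the authors' Feature Extraction run had background-subtracted and spatially detrended, with flags for spots well above background and for outlier spots. They also hold the median raw intensity and background of each spot. The deposited series values are linear intensities that the authors had averaged over the 4 spots of each probe and scaled per array, as found from the values: the 75th percentile of every array lay between 4994 and 5040. The authors' scaling step itself is not given in the sources used here.

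The arrays lay on 26 slides of at most 4 arrays and were scanned on 11 days. The 75th percentile of the processed signal ranged from 766 to 3092 between arrays (median 2330), and flagged outlier spots made up 1.50% to 4.17% of an array. The deposited series values correlated with the per-array files at r of at least 0.998 across probes, which are not independent replicates.

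The 41584 spots gave 10396 probes, 39 with a gene symbol and the rest with contig or clone IDs. The files do not pair these IDs with gene names, and no annotation table was used. So 24 lists of pathways and the tissue marker lists, written as annotation text before the data were examined, could not be matched and were not tested. The symbols gave 5 lists. They were the mevalonate pathway (8 probes), the MEP pathway (4 DXS probes), prenyl diphosphates (5 probes for IPPI, GPPS and GGPPS), EuTPL (5 probes) and EuAc (6 probes). The last pair was grouped by probe name, after the names but before any value was seen. The MEP list holds fewer than 5 probes and is given as values only.

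For the main fits, the log2 processed signal of the spots not flagged as outliers was averaged per probe, and the 75th percentile of the array was subtracted. Probes were kept where they were well above background on at least as many arrays as the smallest group compared has, and on at least 3 for trends and for cells of single arrays. Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend or robust options). Tests were two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. Tables were handled with the R package data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A fold is given as "at least" where a group lay at background, against the lowest level well above background on each array.

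The comparisons were inner against outer current-year stem, male against female flowers, immature fruit against female flowers, and female against male leaves of the same month and day (8 pairs) with date as a block. In the pair of 11 April the labels give 2009 for the female and 2008 for the male leaf. Seasonal slopes per 30 days were fitted in immature fruit and in leaves, and the leaf slope was compared between the sexes. Each of 6 tissues was contrasted with the unweighted mean of the other 5, and a probe was called enriched where it also exceeded each other tissue by at least 1 log2 unit past the threshold. In the hormone series each treated arm was compared with the untreated arm over 3, 6, 12 and 24 h with time as a block, IAA plus NPA with IAA, and 3 h and 24 h with 0 h with arm as a block. The labels give 10 µM IAA, 20 µM NPA, 10 µM ABA, and 20 mM NPA in the combined arm. In the leaf series the change from 0 h was compared between the heat series (37 and 42 °C), the cold series (15 °C), light and dark, relative to the 27 °C series. The 2nd year stem pair, the fruit wing, the fruit without its wing and the 2 leaf buds are single arrays and enter no test.

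Lists of at least 5 probes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The genes named in the text follow a rule. It takes the 8 largest rises and the 8 largest falls among probes past the threshold with a gene name, up to 4 members with the smallest adjusted p of each list that passes camera, and up to 4 mevalonate, MEP and prenyl members past the threshold with the smallest adjusted p. Of the probes without a name, at most the 2 largest rises and 2 largest falls are given by ID. A text paragraph may name fewer.

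The groups, the main tests, the rule for named genes and the first set of alternatives were chosen before the data were examined. These alternatives were normexp background correction with an offset of 50, run on median signals because mean signals are not in the files used, quantile normalization, no filter or a filter on every array, the authors' series values, slide as a random block, probes averaged per annotation, replicate blocks, and leaving out each replicate of the stem parts and male flowers, each time, arm or series, or dated samples. Slide and scan day as fixed blocks, scan day as a random block and leaving out immature fruit replicate 12 were added after the data had been seen. Slides and scan days were read from the file headers and are numbered here.

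Stem replicates share numbers and dates in the labels. Deviations from the group means of same-numbered inner and outer samples correlated across probes at r between 0.538 and 0.750, so these were treated as pairs in the alternative fit with a replicate block. Other splits of the samples into groups of the same sizes were refitted, at most 100 per comparison. The fitting code was tested on simulated data with 200 probes changed. It recovered 60.0% of the probes changed by 2 log2 units between the stem tissues, 53.5% between the flowers, 81.0% between fruit and female flowers, and 96.0% between the leaves of the sexes. For a change of 1 log2 unit these shares were 3.00%, 0.00%, 50.0% and 76.5%, so the main fits would mostly miss changes of that size between the stem tissues or the flowers. The main stem fit does not use the pairs, and the alternative fit with a replicate block was not simulated.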

Results

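Transcript levels were measured in Eucommia ulmoides, a tree that makes trans-polyisoprene rubber, on 102 one-colour Agilent arrays with 1 sample per array. The tissues were current-year inner stem (n = 5) and outer stem (n = 5), female flowers (n = 6), male flowers (n = 3), immature fruit (n = 12), and leaves of male (n = 11) and female (n = 8) trees. A further 6 arrays were single samples: inner and outer 2nd year stem, a fruit wing, a fruit without its wing, and a male and a female leaf bud. Immature fruit sampled on 30 May gave 25 arrays, 5 arms at 0, 3, 6, 12 and 24 h. The arms were untreated, indole-3-acetic acid (IAA, an auxin), N-1-naphthylphthalamic acid (NPA, an inhibitor of polar auxin transport), both together, and abscisic acid (ABA). Leaves under heat, cold, light or darkness gave 21 arrays, 7 series at 0, 3 and 24 h.

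Of the 10396 probes, 39 carried a gene symbol, and a number after a symbol tells apart probes that share it. The other probes carried clone or contig IDs that the files do not pair with gene names. Levels are log2 intensities relative to the 75th percentile of their array, given as mean ± SD (n), and differences carry the standard error (SE) and the adjusted p of limma's moderated test (two-sided). Between 76.3% and 95.9% of the probes lay well above background on an array (median 90.3%), and the number of arrays limits the precision. Counts of list members past the threshold are over all probes tested. Where such a count is given, adjusting over the list alone gave the same count unless a further one is stated. The labels do not state that replicates come from different trees, so the p-values measure only the spread between these samples.

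The tissue comparison asked which transcripts mark each of 6 tissues, by contrasting each with the mean of the other 5 over 10173 probes. All stems and male flowers are labelled male, all female flowers and fruit female, and only leaves hold both sexes. Sampling dates also differ between the tissues, so tissue, sex and date are mixed in these contrasts. A probe was called enriched where it was also past the threshold and at least 1 log2 unit above each other tissue. By this rule 210 probes were enriched in leaves, 66 in inner stem, 165 in outer stem, 44 in female flowers, 341 in male flowers and 49 in immature fruit. With slide as a fixed block the numbers were 791, 26, 88, 0, 134 and 0, where limma left 1297 probes for female flowers and 3673 for fruit at an unadjusted p under 0.05. With scan day as a fixed block they were 917, 56, 159, 4, 210 and 12. Leaving out inner stem replicate 3 or 5 gave 38 or 111 probes for inner stem, and leaving out inner stem replicate 5 or male flower replicate 3 gave 29 for female flowers.

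In leaves, EuTPL1 stood at 4.55 ± 1.20 (n = 19), 3.93 above the other tissues (SE 0.47, adjusted p = 2.13e-09; 19 of 19 leaves). The mean of the other tissues includes outer stem, whose low level, given below, enlarges this difference. The difference was 10.25 with scan day as a fixed block, and it kept its call in 24 of 24 alternatives, so its size but not its direction depends on the batch model. IPPI, GPPS and GGPPS make the prenyl diphosphates from which isoprenoids are built. The list of these 5 prenyl probes was higher in leaves by camera (adjusted p = 0.0384; adjusted p = 0.0455 with an estimated correlation; 0.0778 after quantile normalization). Of its members 2 rose over all probes and 4 when adjusted over the list alone. EuIPPI was at 3.66 ± 0.65 (n = 19), 1.40 higher (adjusted p = 1.9e-08; 18 of 19), and GGPPS 4686 at 0.77 ± 0.33 (n = 19), 0.74 higher (adjusted p = 2.4e-06; 18 of 19; 1.42 with slide and 1.46 with scan day as a fixed block). The list's mean shift was 0.78, against 1.06 with slide and 0.63 with scan day as a block. Of the mevalonate probes, 5 of 8 were lower in leaves. RB030_A22.b (8.54) and RB057_A21.b (7.45) were the largest rises, in 19 of 19 leaves. Across all probes the median leaf difference was -0.17.

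In outer stem EuTPL1 was at -5.99 ± 2.00 (n = 5), a difference of -8.72 from the other tissues (SE 0.75, adjusted p = 4.8e-13; 5 of 5). The EuTPL list fell as a set (camera adjusted p = 0.00045; 0.0295 with an estimated correlation), with 4 of 5 members lower. The prenyl list fell too (camera adjusted p = 0.0257; 0.0295 with an estimated correlation; 0.0508 after normexp background correction), through GPPS (-4.00), EuIPPI (-1.42) and GGPPS 10475 (-1.09). GGPPS 10475 lost its call with scan day as a fixed block (-0.13) and turned to 0.24 with slide. GPPS lost its call without outer stem replicate 3 (adjusted p = 0.0626) or 5 (0.0536), with 0.00212 to 0.0626 over its alternatives. EuTPL5 (-4.57) lost its call without outer stem replicate 5 (adjusted p = 0.0531; 0.00468 to 0.0564 over its alternatives). Mean shifts were -3.41 for EuTPL (-5.03 with slide and -5.26 with scan day as a block) and -1.52 for the prenyl list (-3.05 and -2.57). In inner stem, SQS, the squalene synthase that leads to sterols and triterpenes, was at 2.85 ± 0.34 (n = 5), 1.64 above the others (SE 0.22, adjusted p = 2.61e-07; 5 of 5; 0.96 with scan day as a fixed block). EuIPPI fell by 1.07 in inner stem (adjusted p = 0.0112; 0.0973 without inner stem replicate 5, and 6.91e-05 to 0.0973 over its alternatives).

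HMGS and HMGR catalyse early steps of the mevalonate pathway, HMGR the rate-limiting one, and MK, PMK and MPD the later ones. In female flowers 5 of 8 mevalonate probes rose, 1 fell when adjusted over the list alone, and the list rose as a set (camera adjusted p = 0.0232; adjusted p = 0.336 with an estimated correlation). HMGS 10370 was at 4.14 ± 0.17 (n = 6), 2.58 above the other tissues (SE 0.56, adjusted p = 0.000906; 6 of 6). The list's mean shift was 0.82, or 0.94 with slide and 1.20 with scan day as a block. EuTPL5 was 7.48 higher (SE 1.36, adjusted p = 0.000128; 6 of 6) and the EuTPL list rose as a set (camera adjusted p = 0.0208; adjusted p = 0.249 with an estimated correlation), with shifts of 2.40, 1.31 and 2.07. HMGS 10370 and EuTPL5 each kept their call in 22 of 24 alternatives and lost it with slide as a random block (1.88 and 5.86) or a fixed one (1.41 and 3.38).

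In male flowers EuHMGR was enriched, at 2.68 ± 1.77 (n = 3), 2.31 above the other tissues (SE 0.38, adjusted p = 7.02e-06; 3 of 3). Without male flower replicate 3 this was 1.30 (adjusted p = 0.0102; 1.86e-07 to 0.0102 over its alternatives) and no longer enriched, and HMGR 8220 went from 1.33 to 0.60 and lost its call. EuAc4 likewise went from 3.74 to 1.80 and lost its call. The mevalonate list rose as a set (camera adjusted p = 0.0360; adjusted p = 0.480 with an estimated correlation, 0.138 after normexp, 0.0581 after quantile normalization), with 3 of 8 members past the threshold over all probes and 5 adjusted over the list alone. Its shift was 0.94, or 1.00 with slide and 1.05 with scan day as a block. DXS makes the first intermediate of the plastid MEP pathway, and 3 of 4 DXS probes fell in male flowers. In immature fruit SQS was at 0.38 ± 0.54 (n = 12), a difference of -1.32 (SE 0.16, adjusted p = 1.88e-08; 12 of 12), and EuHMGR at -0.30 ± 0.20 (n = 12), a difference of -1.27 (adjusted p = 2.42e-05; 12 of 12). EuHMGR in fruit lost its call with scan day as a fixed block (-0.60).

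**Figure D1:**
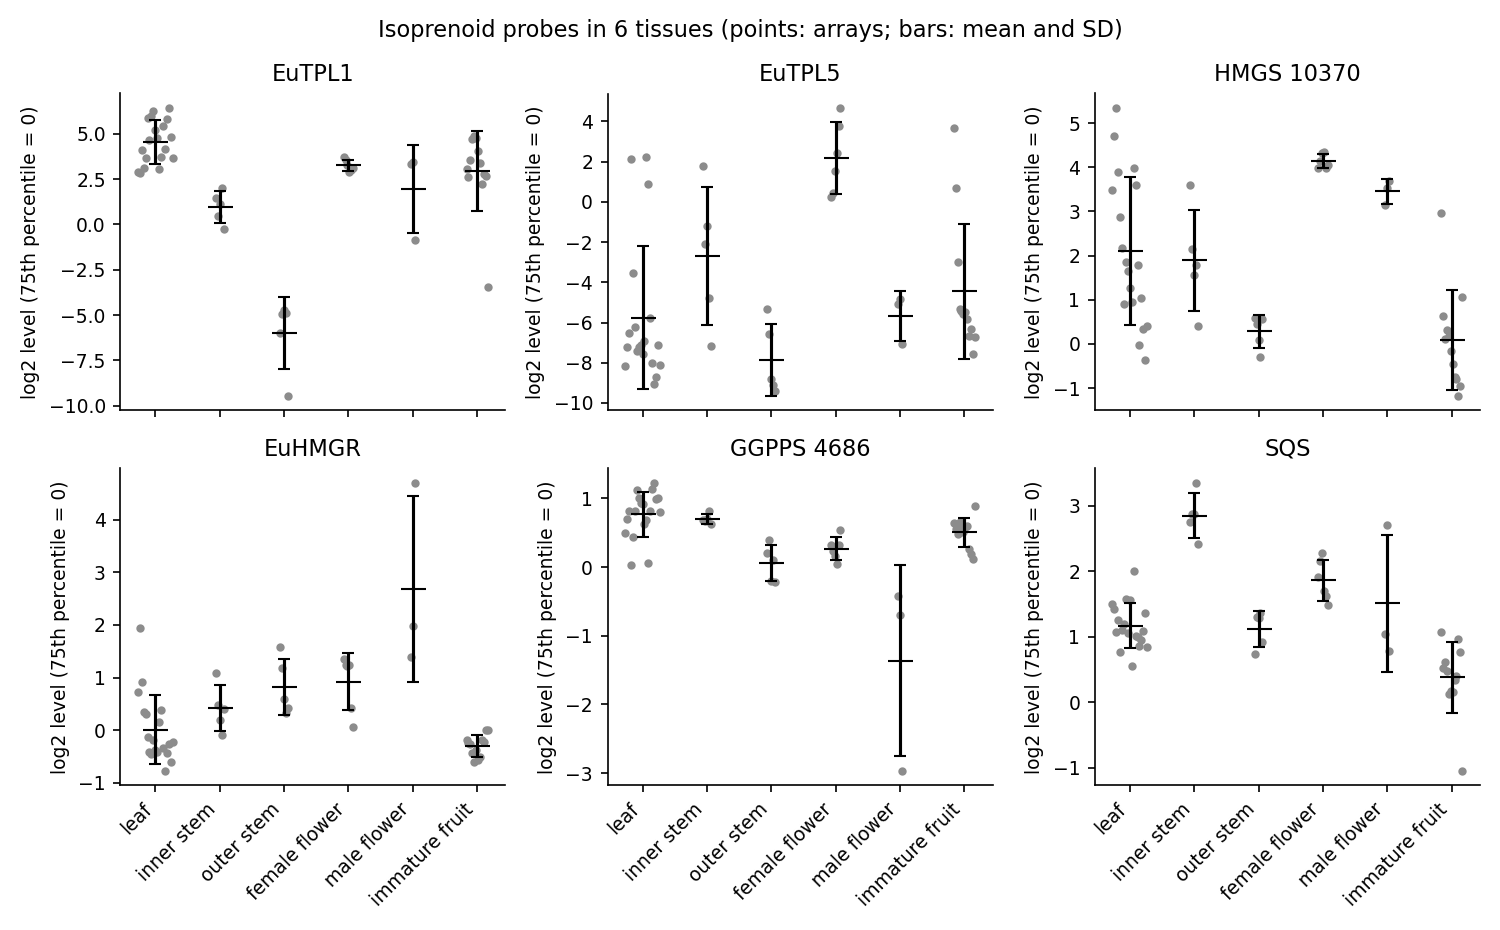
Log2 levels relative to the 75th percentile of each array for named probes in 6 tissues; points are arrays and bars mark the mean and SD. EuTPL1 runs from a mean of -5.99 in outer stem to 4.55 in leaves.

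Inner and outer stem of the current year were compared at 5 dates to ask which transcripts separate the 2 parts. Of 9696 probes, 342 were higher and 185 lower in inner stem, 527 in all, and 502 of them differed at least 2-fold. Each inner sample correlated best, across probes, with the outer sample of its own number and date, and with these pairs as a block 2110 probes were called. EuTPL1 was at 0.95 ± 0.87 (n = 5) in inner and -5.99 ± 2.00 (n = 5) in outer stem, a difference of 6.94 (SE 0.89, adjusted p = 0.00132; 5 of 5). The EuTPL list was higher in inner stem by camera (adjusted p = 0.00378; adjusted p = 0.237 with an estimated correlation), with 1 of 5 members past the threshold and 3 adjusted over the list alone. SQS was at 2.85 ± 0.34 against 1.12 ± 0.27 (n = 5 each), a difference of 1.73 (SE 0.23, adjusted p = 0.00148; 5 of 5). Contig2161 (9.75) and Contig888 (9.68) rose most, while Contig2339 was at least 1174-fold lower and Contig4005 at least 1749-fold lower.

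The calls between the stem parts had the same sign in 100% of cases within slide 1, within slide 2 and within scan day 1. These arrays also made the calls, and scan day 1 holds all current-year stem arrays but those of 13 January. The agreement was thus largely built in and is no independent check. With slide or scan day as a fixed block 1372 and 827 probes were called, and 883 without the pair of 13 January. Each array of 13 January is the only stem array on its slide and scan day, so both blocks take that pair out of the contrast. The scan day fit is thus the fit without that pair, but for the probe filter. The slide fit adds only a block for slides 1 and 2. The EuTPL shift was 2.94, or 2.99 with slide as a block and 2.87 and 3.11 within slides 1 and 2. In the single 2nd year pair, with no replicates, 9 of the 527 probes (1.71%) had the current-year sign, with a slope of -1.03 across these probes, which are not independent replicates. A current-year pair left out of the fit gave between 89.9% and 100%. These values cannot tell which set of labels is right, and the stem directions given here rest on the current-year labels.

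**Figure D2:**
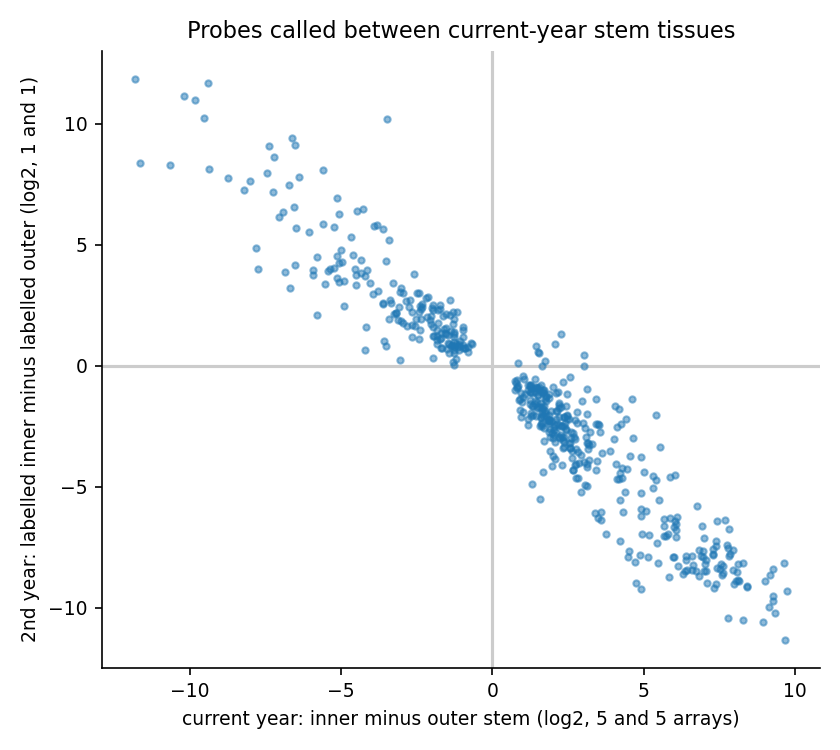
Log2 difference between the 2nd year libraries labelled inner and outer against the mean current-year difference, with 1 point per called probe. Of 527 probes, 9 have the same sign on both axes.

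Male and female flowers were compared for transcripts that differ by sex. Of 9779 probes, 687 were higher and 1387 lower in male flowers, and 1831 differed at least 2-fold. The median of all probes lay at -0.19, and quantile normalization made 51.5% of the calls higher against 33.1% here. DXS 12602 was at -1.87 ± 1.68 (n = 3) in male and 0.75 ± 0.21 (n = 6) in female flowers, a difference of -2.63 (SE 0.59, adjusted p = 0.0145; 3 of 3). Without male flower replicate 3 that difference was -1.65, still past the threshold. The probe named gDNA, dim in all flowers, was lower in male flowers by 1.33 (adjusted p = 0.0207) and turned to 0.28 with no call after normexp. All 3 tested MEP probes fell, and EuIPPI rose from 2.22 ± 0.45 (n = 6) to 3.69 ± 0.77 (n = 3), by 1.46 (SE 0.38, adjusted p = 0.0266; 3 of 3). EuIPPI lost its call without male flower replicate 2 (adjusted p = 0.0762) or 3 (0.0680), with 0.0118 to 0.383 over its alternatives. EuTPL5 was at -5.66 ± 1.24 (n = 3) against 2.19 ± 1.78 (n = 6), a difference of -7.85 (SE 1.02, adjusted p = 0.00149; 3 of 3). RB035_A06.b was at least 212-fold higher and RT034_P03.b 8.31 higher in male flowers, and Contig2092 was at least 88.8-fold lower. Male flowers were sampled from 24 March to 11 April and female flowers from 8 April to 27 May, so sampling date and sex are mixed. No slide or scan day held both kinds of flower, so batch and sex cannot be told apart here. With slide or scan day as a random block 94 probes were called. Under these blocks EuTPL5, RB035_A06.b and Contig2092 kept their calls, while DXS 12602 (-2.99), EuIPPI (1.49) and RT034_P03.b (8.89) lost theirs.

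Immature fruit and female flowers were compared to ask what changes as flowers give way to fruit. Of 9694 probes, 2056 were higher and 2183 lower in fruit, and 2215 differed at least 2-fold. Of the mevalonate probes 5 of 8 fell and 1 rose, and the list fell as a set (camera adjusted p = 0.0201; adjusted p = 0.234 with an estimated correlation). HMGS 10370 was at 0.08 ± 1.13 (n = 12) in fruit and 4.14 ± 0.17 (n = 6) in flowers, a difference of -4.05 (SE 0.45, adjusted p = 6.8e-06; 12 of 12). EuHMGR was at -0.30 ± 0.20 against 0.92 ± 0.54, a difference of -1.22 (SE 0.18, adjusted p = 5.18e-05; 12 of 12), whereas HMGR 8220 rose by 0.55 (adjusted p = 0.0206). SQS fell by 1.48 (SE 0.24, adjusted p = 0.000123; 12 of 12) and GPPS by 3.17 (SE 0.72, adjusted p = 0.00194; 12 of 12). The EuTPL and EuAc lists each fell as a set (camera adjusted p = 0.0402; adjusted p = 0.301 with an estimated correlation), with 3 of 5 and 4 of 6 members lower. RB021_O19.b (8.70) and Contig2278 (7.98) rose most, and Contig1120 was at least 400.2-fold lower.

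Slide 5 and scan day 3 held both fruit and female flowers. Their flowers were the latest, of 13 and 27 May, and the fruit of slide 5 the earliest, of 10 and 24 June. Batch and date are therefore mixed in these values and in the fits with slide or scan day as a block. On slide 5 and scan day 3, 88.5% and 92.3% of the called probes had the same sign, which is partly built in because these arrays also made the calls. The differences were smaller there, with slopes of 0.35 and 0.53 on the reported ones. With slide or scan day as a fixed block 195 and 2040 probes were called. The mevalonate shift was -1.14, or -0.95 with slide and -1.37 with scan day as a block. The EuTPL shift was -1.89, or -0.79 and -1.44, and the EuAc shift -1.08, or -0.29 and -0.28. Under the slide block HMGR 8220 turned to -0.06 with no call. Under that block EuHMGR (-0.46), SQS (-0.76) and GPPS (-1.76) also lost their calls, and HMGS 10370 (-2.21) and Contig1120 (-3.95) kept theirs with smaller differences. RB021_O19.b (4.22) and Contig2278 (1.73) lost their calls under it, and Contig2278 (2.94) also with slide as a random block. GPPS (-1.57) and rRNA (-0.82) lost theirs with scan day as a block. The rRNA probe was at 0.31 ± 0.61 (n = 12) in fruit and 2.15 ± 1.40 (n = 6) in flowers, a difference of -1.84 (adjusted p = 0.00287; 12 of 12).

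The fruit season was followed over 12 arrays and 140 days as a slope per 30 days. Of 9659 probes, 1153 rose and 1730 fell. PLR fell by 0.59 per 30 days (SE 0.08, adjusted p = 0.000351), EuTPL5 by 1.72 (SE 0.32, adjusted p = 0.00260) and GAPDH 12321, a glycolytic enzyme, by 0.99 (SE 0.27, adjusted p = 0.0190). Of the EuAc probes 3 of 6 fell over all probes and 5 adjusted over the list alone, EuAc5 by 0.55 (SE 0.09, adjusted p = 0.00103). Among prenyl probes GGPPS 10475 rose by 0.34 (SE 0.10, adjusted p = 0.0270), and in the mevalonate list PMK fell by 0.21 (adjusted p = 0.0269) and MPD by 0.20 (adjusted p = 0.0326), 2 of 8 members, or 3 adjusted over the list alone. Without immature fruit replicate 12, MPD (-0.16, adjusted p = 0.0592) and EuAc4 (-0.20, adjusted p = 0.0722) lost their calls, with ranges of 0.0257 to 0.865 and 0.0390 to 0.840 over their alternatives. Without that array GAPDH 12321 fell by 0.61, GGPPS 10475 rose by 0.19 and PMK fell by 0.13, all past the threshold. After normexp PLR (-0.08) and EuAc5 (-0.22) lost their calls. Slides and scan days follow the season, and with them as a fixed block limma called 0 probes by slide (1095 at an unadjusted p under 0.05) and 773 by scan day. RB018_E09.b (1.93) and RB057_O23.b (1.69) rose most, and Contig2894 (-3.17) and Contig2297 (-2.90) fell most. Quantile normalization made 64.3% of the calls rises, against 39.99% here.

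Female and male leaves were compared in 8 pairs of the same month and day to ask which transcripts differ by sex outside flowers. In the pair of 11 April the female leaf is labelled 2009 and the male leaf 2008. Of 9506 probes, 407 were higher and 506 lower in female leaves, and 257 differed at least 2-fold. Contig2092 was at least 110.4-fold higher and RT043_K05.b at least 84.0-fold higher in female leaves, each in 8 of 8 pairs. RB035_A06.b was at least 270.4-fold lower and Contig1807 at least 50.5-fold lower, also in 8 of 8 pairs. PLR was at -7.37 ± 1.52 in female and -5.56 ± 1.43 in male leaves (n = 8 each), a difference of -1.81 (SE 0.49, adjusted p = 0.0440; 7 of 8). The female level of PLR lies near background, where the size of a difference is uncertain. RB035_A06.b at -7.68 was not well above background in fruit of 10 June. EuAc6 differed by -0.65 (SE 0.17, adjusted p = 0.0418; 7 of 8), 1 of 6 EuAc probes, or 2 adjusted over the list alone. Without the pair of 11 April PLR (adjusted p = 0.0662; 0.0191 to 0.942 over its alternatives) and EuAc6 (0.0669; 0.0187 to 0.935) lost their calls. Within slide 10, scan day 5 and scan day 7, the calls had the same sign in 67.9%, 83.0% and 100% of cases. These arrays also made the calls, so part of the agreement was built in. Slide 10 set male leaves of 11 and 28 April against female leaves of 24 June and 22 July, so sex and season are mixed there. Scan day 5 set the same male leaves against female leaves of April to July, and on scan day 7 the dates matched. With slide or scan day as a fixed block 13 and 684 probes were called.

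**Figure D3:**
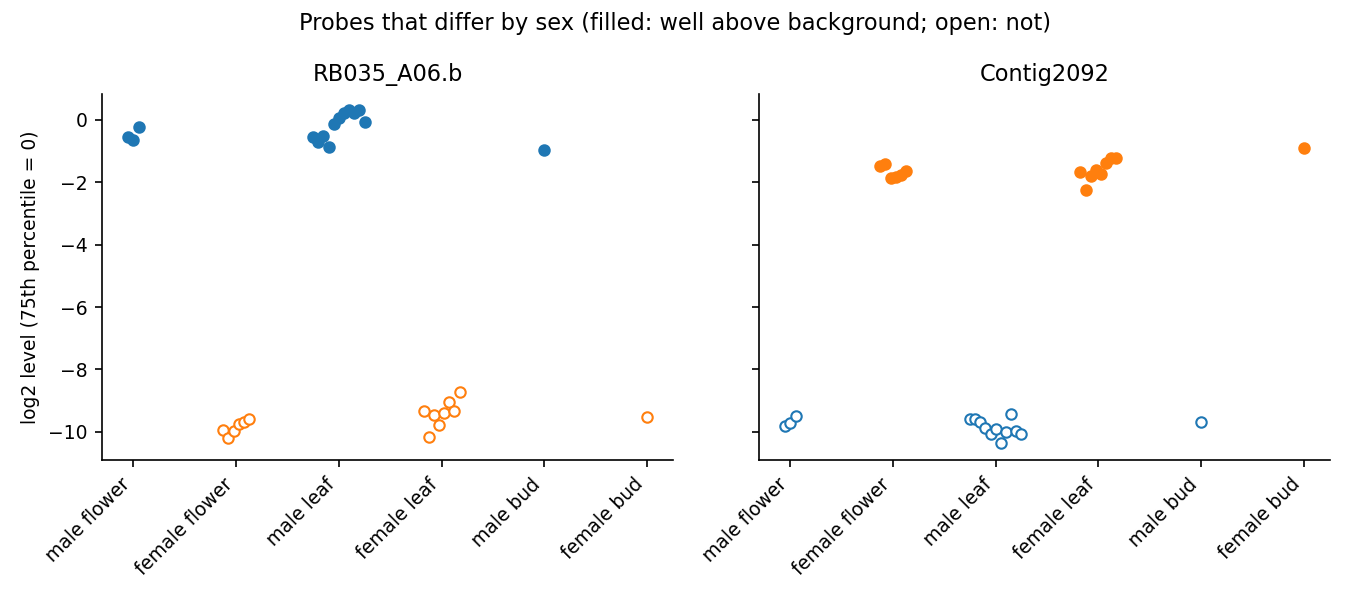
Log2 levels relative to the 75th percentile of each array for probes that differ by sex, in flowers, leaves and leaf buds of each sex; points are arrays, filled where well above background. RB035_A06.b lies well above background in no female sample shown and is at least 212-fold higher in male flowers and at least 270.4-fold higher in male leaves.

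The leaf season was followed over 200 days as a slope per 30 days. Of 9855 probes, 1659 rose and 2541 fell. The fit takes the male and female leaf of a date as independent samples, so its p-values and counts do not allow for what leaves of 1 date share. DXS 12602 fell by 0.46 per 30 days (SE 0.05, adjusted p = 1.34e-05) and DXS 13333 by 0.38 (SE 0.07, adjusted p = 0.00043), 2 of 3 MEP probes tested. In the mevalonate list 3 of 8 probes fell, HMGS 10370 by 0.47 (SE 0.09, adjusted p = 0.000806), and none of the 3 kept its call without the April arrays, where EuHMGR turned to 0.0039 and HMGR 13453 to 0.08. Of the EuAc probes 5 of 6 fell, and the list fell as a set (camera adjusted p = 0.0150; adjusted p = 0.282 with an estimated correlation), with a shift of -0.25 that was -0.03 with slide and -0.09 with scan day as a block. EuTPL5 fell by 1.25 (SE 0.29, adjusted p = 0.00285), and ABP1, an auxin-binding protein, by 0.16 (adjusted p = 0.000647). Without the April arrays 4812 probes were called, 2638 of them shared, and EuTPL5 (-0.17, adjusted p = 0.320; 0.00213 to 0.632 over its alternatives) and HMGS 10370 (-0.19, adjusted p = 0.0909; 0.00055 to 0.666) lost their calls. Of the other EuAc members, EuAc4 moved from -0.44 to -0.25. DXS 13333 lost its call after normexp (-0.20) and with scan day as a block (-0.36), and ABP1 with scan day as a block (-0.19). With slide as a fixed block limma called 0 probes (1084 at an unadjusted p under 0.05), and with scan day 491. Normexp correction made 53.2% and quantile normalization 54.0% of the calls rises, against 39.5% here. Between the sexes limma called 0 of 9855 slopes different, with 411 at an unadjusted p under 0.05. In simulated data this fit recovered 5.5% of slope differences of 0.25 per 30 days and 51.5% of those of 0.5. The lack of calls therefore does not show that the slopes are equal.

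The fruit arms were compared with the untreated arm over 3, 6, 12 and 24 h, with time as a block, to ask how auxin, its transport and ABA change fruit transcripts. In the IAA arm 2256 of 9737 probes were higher and 913 lower, 382 of them at least 2-fold. DXS 12602 was at 1.85 ± 0.39 against 1.28 ± 0.49 (n = 4 each), a difference of 0.57 (SE 0.08, adjusted p = 0.000842; 4 of 4). HMGR 13453 was at -0.32 ± 0.19 against 0.32 ± 0.53, a difference of -0.64 (SE 0.11, adjusted p = 0.00247; 4 of 4). EuAc3 was 1.33 higher (SE 0.27, adjusted p = 0.00408; 3 of 4). Of the MEP probes 2 of 4 rose and of the mevalonate probes 3 of 8 fell. The rRNA probe was lower too, by 0.36 (adjusted p = 0.0145), and turned to 0.25 relative to the 0 h arrays. Contig4116 (3.37) rose most, and RB028_J02.b was at least 4.54-fold lower. At 0 h, before any treatment time had passed, 95.5% of the called probes already differed from the untreated arm with the same sign. Relative to each arm's own 0 h array, a single array whose error that fit leaves out, 633 probes came out higher and 1032 lower, and HMGR 13453 turned to 0.21 and EuAc3 to -0.54, while DXS 12602 stayed at 0.48. Without 3, 6, 12 or 24 h the count was 1232, 266, 54 or 5219. HMGR 13453 and EuAc3 lost their calls without 6 h (-0.51 and 1.22) or 12 h (-0.61 and 1.16), and RB028_J02.b without 3, 6 or 12 h (-2.87, -2.94 and -4.58), while DXS 12602 kept its call without any one time. With slide and scan day as fixed blocks the count was 3 and 4. Of the calls 84.3% kept their sign within slide 15 and 83.7% within scan day 8, checked on arrays that also made the calls. In both the untreated side is 1 array, that of 24 h, so arm and time are mixed there.

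In the NPA arm 1628 probes were higher and 666 lower. HMGR 13453 fell by 0.73 (adjusted p = 0.00232; 4 of 4) and HMGS 10370, at 3.12 ± 0.14 against 3.55 ± 0.06 (n = 4 each), by 0.43 (adjusted p = 0.00964; 4 of 4). The mevalonate list fell as a set (camera adjusted p = 0.0162; adjusted p = 0.336 with an estimated correlation, 0.156 after quantile normalization), with 2 of 8 members past the threshold. EuAc3 rose by 1.39 (adjusted p = 0.00510; 4 of 4). Of the called probes 88.2% had the same sign at 0 h. Without 3, 6, 12 or 24 h the count was 645, 11, 14 or 4015. HMGR 13453 lost its call without 6 h (-0.63) or 12 h (-0.73), HMGS 10370 without 3, 6 or 12 h (-0.39, -0.47 and -0.44) and EuAc3 without 3, 6 or 12 h (1.21, 1.26 and 1.24). Relative to each arm's own 0 h array HMGR 13453 was at -0.09 with no call and EuAc3 turned to -0.13, while HMGS 10370 stayed at -0.41. That baseline too is 1 array per arm. No fit with slide or scan day as a fixed block could be had, so NPA and batch cannot be told apart.

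In the combined IAA plus NPA arm 2203 probes were higher and 906 lower. DXS 12602 rose by 0.37 (adjusted p = 0.00309; 4 of 4) and HMGR 13453 fell by 0.33 (adjusted p = 0.0364; 3 of 4), and the rRNA probe by 0.40 (adjusted p = 0.00757), which turned to 0.46 relative to the 0 h arrays. At 0 h 94.4% of the called probes had the same sign, and relative to each arm's own 0 h array DXS 12602 turned to -0.02 and HMGR 13453 to 0.43, where the baseline is 1 array per arm and its error is left out. Without 3, 6, 12 or 24 h the count was 1755, 893, 643 or 4760. DXS 12602 lost its call without 12 h (0.33), and HMGR 13453 without 3, 6 or 12 h (-0.28, -0.23 and -0.30), while without 24 h it was at -0.52. With slide and scan day as fixed blocks the count was 1 and 190. Of the calls 87.4% kept their sign within scan day 8, again on arrays that also made the calls and against the untreated array of 24 h alone. Against IAA alone 6 probes differed, with 1050 at an unadjusted p under 0.05. RT036_K18.b was 1.80 higher (SE 0.28, adjusted p = 0.0325; 4 of 4) and Contig4116 was lower, at -1.46 (SE 0.22, adjusted p = 0.0273; 4 of 4). All these arrays share scan day 8, and on slide 16, the only slide with both, arm and time are mixed. The count without 3, 6, 12 or 24 h was 2, 0, 0 or 20, where limma left 557 and 398 probes at an unadjusted p under 0.05 without 6 and 12 h. RT036_K18.b lost its call without 3, 6 or 12 h (1.89, 1.80 and 1.44), and Contig4116 without any one time (-1.60, -1.59, -1.27 and -1.36). The counts with slide and scan day as fixed blocks were 1 and 133.

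In the ABA arm 2463 probes were higher and 880 lower. DXS 12602 was at 0.93 ± 0.38 against 1.28 ± 0.49 (n = 4 each), a difference of -0.35 (adjusted p = 0.00401; 4 of 4), opposite to the IAA arm. GGPPS 10475 fell by 0.36 (adjusted p = 0.00258; 4 of 4) and HMGR 13453 by 0.53 (adjusted p = 0.00352; 4 of 4), and the rRNA probe fell by 0.30 (adjusted p = 0.0306; 0.47 relative to the 0 h arrays). At 0 h 94.1% of the called probes had the same sign, and relative to each arm's own 0 h array DXS 12602 turned to 0.05 and HMGR 13453 to 0.14, while GGPPS 10475 stayed at -0.29, again with a baseline of 1 array per arm. Without 6 or 12 h the count was 441 or 339. Without 6 or 12 h DXS 12602 (-0.29 and -0.37), GGPPS 10475 (-0.35 and -0.32) and HMGR 13453 (-0.44 and -0.49) lost their calls. No fit with slide or scan day as a fixed block could be had, so ABA and batch cannot be told apart. In the 4 arms between 70.9% and 73.7% of the calls were higher, and quantile normalization brought this to between 46.6% and 51.4%.

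**Figure D4:**
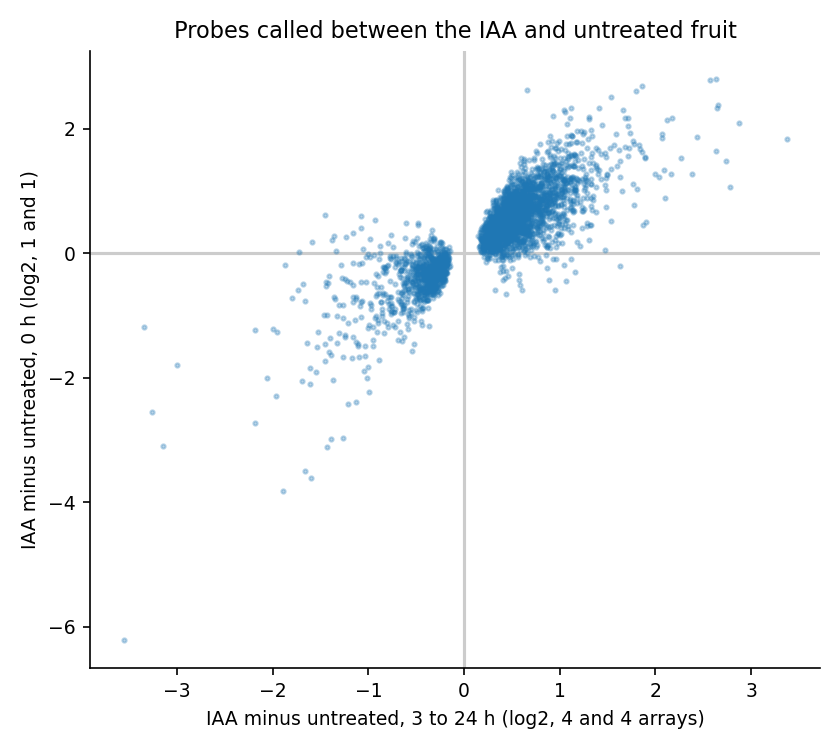
Log2 difference between the IAA and untreated arms at 0 h against the mean difference over 3 to 24 h, with 1 point per probe called for IAA. The sign is the same for 95.5% of the probes.

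Fruit at 3 h and 24 h was compared with 0 h over the 5 arms to ask what changes with time after sampling. At 3 h limma called 3 of 9825 probes, RT017_E05.b (0.66), Contig405 (-0.51) and RB020_I06.b (-0.30), with 1986 at an unadjusted p under 0.05. Without any one arm the count was 0, with between 1070 and 2071 probes at an unadjusted p under 0.05, and with slide and scan day as fixed blocks it was 190 and 24. At 24 h 2374 probes were higher and 2853 lower, 904 of them at least 2-fold, and 4966 and 5723 were called with slide and scan day as fixed blocks. DXS 12602 went from 2.12 ± 0.28 to 0.76 ± 0.36 (n = 5 each), a difference of -1.36 (SE 0.08, adjusted p = 3.11e-09; 5 of 5). Of the 4 MEP probes 3 fell, while DXS 8480 rose by 1.53 (SE 0.28, adjusted p = 0.000169; 5 of 5). GGPPS 14500 went from -0.06 ± 0.78 to 2.21 ± 0.32, a rise of 2.28 (SE 0.32, adjusted p = 1.57e-05; 5 of 5). HMGR 13453 went from 0.22 ± 0.34 to -0.51 ± 0.21, a difference of -0.73 (SE 0.10, adjusted p = 1.68e-05; 5 of 5). EuTPL1 rose by 0.84 (SE 0.14, adjusted p = 5.94e-05; 5 of 5), and 3 of the 5 EuTPL probes fell. RB029_E13.b (4.52) rose most, and RB049_D19.b (-5.82) fell most. DXS 12638, EuIPPI and GGPPS 4686 lost their calls without the IAA arm (adjusted p = 0.196, 0.179 and 0.150), the IAA plus NPA arm (0.128, 0.125 and 0.0855) or the ABA arm (0.0595, 0.153 and 0.0627). Over all their alternatives the ranges were 0.00473 to 0.226, 0.00545 to 0.375 and 0.00332 to 0.150.

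**Figure D5:**
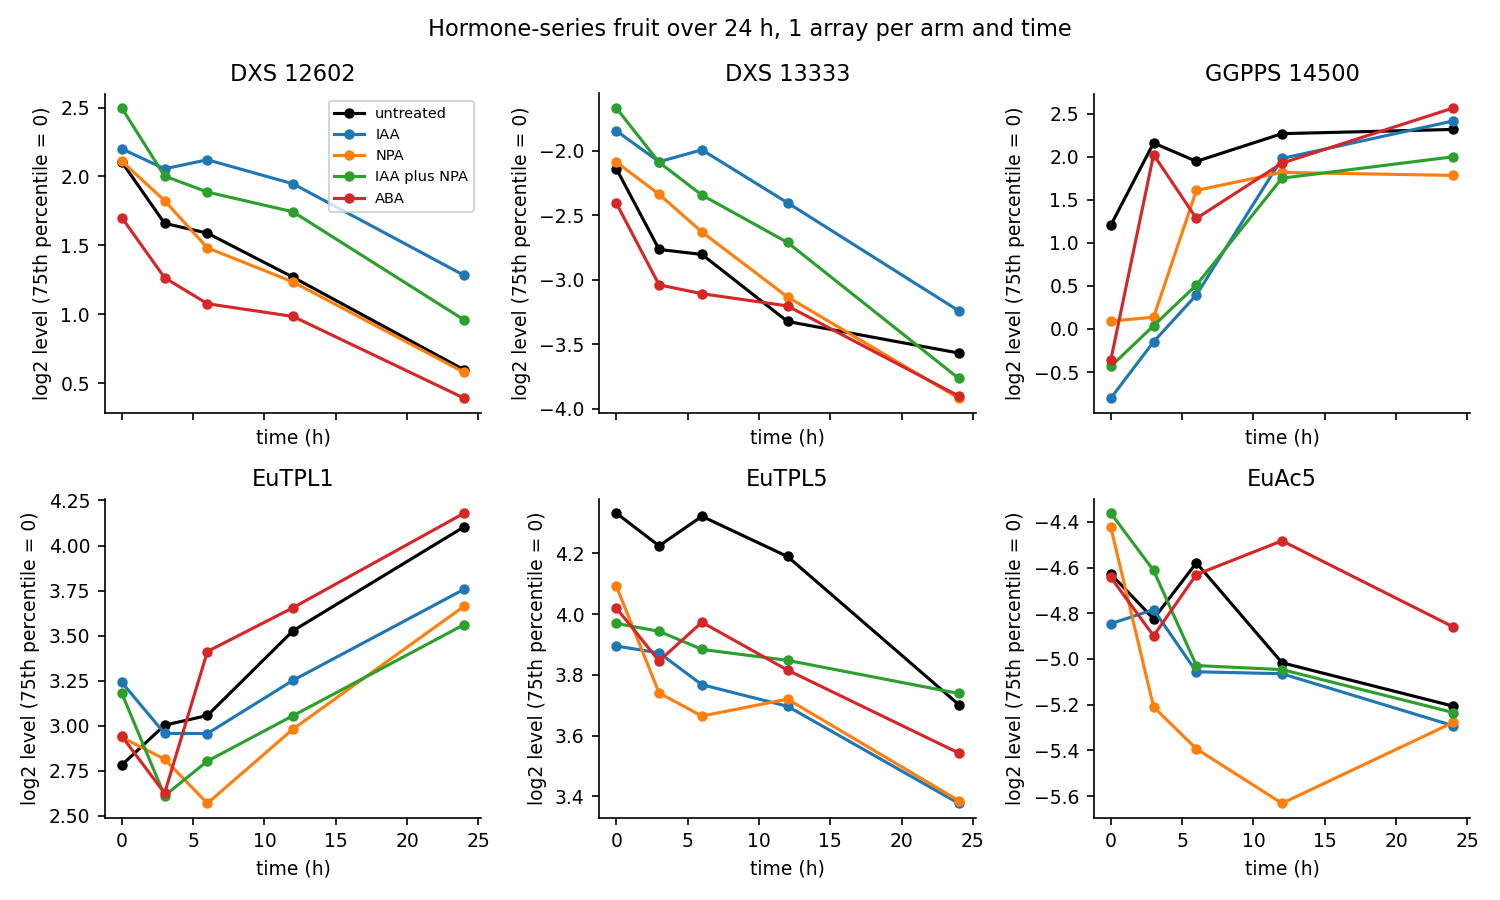
Log2 levels relative to the 75th percentile of each array against hours for named probes in the 5 fruit arms, with 1 line per arm. DXS 12602 falls from a mean of 2.12 at 0 h to 0.76 at 24 h.

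The leaf series asked which transcripts change under heat, cold or light, as changes from 0 h beyond those of the 27 °C series. At 3 h of heat 14 of 9690 probes rose and 18 fell. RT042_P23.b rose by 7.02 (SE 0.87, adjusted p = 0.0314) and RB059_K14.b by 6.21 (SE 0.53, adjusted p = 0.0162), and RB040_M23.b fell by 2.37 and RT061_D19.b by 2.10 (adjusted p = 0.0314 each), each in 3 of 3 heat series. The count was 8 without the 42 °C light series, and 1, 0, 0, 0 and 1 without the 37 °C light, 37 °C dark, 27 °C light, first 27 °C dark or other 27 °C dark series. For the zeros limma left 842, 645 and 1956 probes at an unadjusted p under 0.05. RT042_P23.b was between 6.26 and 7.78 and RB059_K14.b between 5.62 and 6.80 without one of these 37 or 27 °C series, with no call in either case. At 24 h 3 probes rose, among them Contig4165 by 3.09 (adjusted p = 0.0473) and Contig718 by 2.68 (adjusted p = 0.0319), and 1 fell, Contig672 at -1.91 (adjusted p = 0.0319), each in 3 of 3 series. At that time 0 probes were called by limma without any one of those 6 series (545 to 1637 at an unadjusted p under 0.05).

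For cold, a single series at 15 °C, limma called 0 probes, with 1454 at an unadjusted p under 0.05. For light against dark it called 1, Contig294, at -2.05 (SE 0.18, adjusted p = 0.0166), and 0 without any one of the same 6 series (221 to 943 at an unadjusted p under 0.05). With slide as a fixed block limma called 0 probes for heat at 3 h (848 at an unadjusted p under 0.05), heat at 24 h (752) and light (233). Each leaf series was scanned within a single day and already has its own term in the fit. Scan day as a fixed block therefore leaves the fit unchanged, and its counts of 32, 4 and 1 are no check. No probe of the isoprenoid, EuTPL or EuAc lists passed the threshold in any leaf series. In simulated data these fits recovered few of the probes changed by 1 log2 unit. The shares were 17% for heat at 3 h, 8.5% for heat at 24 h, 0% for cold and 27% for light. Changes of that size would mostly be missed, so the lack of calls does not show that these genes stayed unchanged. When adjusted over the list alone, 2 mevalonate probes and 1 EuTPL probe fell at 3 h of heat and 1 MEP probe fell in cold.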

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

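The tests of the 2nd year stem pair, of the hormone arms at 0 h and of the chance overlap of the sex probes were chosen only after the result was seen, as were the fits with slide or scan day as a fixed block and the splits that keep stem pairs, times or arms matched.

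In the 2nd year stem, 9 of the 527 probes called between current-year inner and outer stem (1.71%) had the current-year sign, and the slope of the 2nd year on the current-year difference was -1.03 across these probes. A stem with no tissue difference left would give a slope near 0, and the slope of -1.03 argues against it. Across probes the library labelled inner correlated at r = 0.922 with the outer stem mean and 0.803 with the inner stem mean, and the library labelled outer at 0.953 with inner and 0.832 with outer. Exchanged labels of the pair may explain the 1.71%, since current-year pairs left out of the fit gave 89.9% to 100%. That agreement shows that the current-year pairs are labelled alike, but not that their labels are right. Exchanged labels of all current-year pairs would give the same reversal, and the stem directions reported here rest on those labels. With 1 pair and no replicate, a real reversal in older stem stays open and was not tested.

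Between 88.2% and 95.5% of the probes called for a hormone arm differed from the untreated arm with the same sign at 0 h (95.5% for IAA, 88.2% for NPA, 94.4% for IAA plus NPA and 94.1% for ABA), with slopes of 0.954, 0.869, 1.07 and 0.973. A difference between the arms that was there before treatment may therefore account for much of these calls. Each arm has 1 array at 0 h, so the error of that baseline is unknown. The untreated arrays of 0 to 12 h shared slide 14 and scan day 7 with no treated array, so for NPA and ABA the arm and the batch cannot be told apart, and with slide as a fixed block 3 and 1 probes were called for IAA and IAA plus NPA. Log2 differences of pairs of arms correlated across probes at r between 0.661 and 0.885, against 0.484 to 0.518 simulated with unchanged arms, with covariances of 0.0975 to 0.164 against 0.0156 to 0.0173. Between 1131 and 1642 probes were higher in both arms of a pair, where independent lists would share 368.3 to 570.7, and part of the excess may come from the shared untreated arm.

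Of 9409 probes tested in flowers and leaves, 161 differed by sex in the same direction in both, 1.77 times the 90.8 that independent lists would share, and 81 in opposite directions against 97.02. In the male and female leaf buds, single arrays outside these tests, 137 of the 161 (85.1%) had the same sign, and 38 of the 40 that differed at least 4-fold in both, but the male bud is labelled 2008 and the female bud 2009, so sex and year are mixed there. The buds also lay on different slides and scan days (slides 11 and 12, scan days 6 and 7), so batch and sex are mixed there too. Chance overlap and batches of the arrays could each leave part of the 161 (1.77 and 85.1% decide neither). Of the probes at least 4-fold different in both, 40 went in the same direction and 1 in opposite directions. Flowers of each sex lay on their own slides, so batch cannot be told apart from sex there. In leaves slide 10 and scan days 5 and 7 held both sexes, with dates fully matched only on scan day 7. RB035_A06.b was at least 212-fold higher in male flowers and 270.4-fold in male leaves, and Contig2092 at least 88.8-fold and 110.4-fold lower, and the bud of the sex with the lower level was not well above background for either. Whether sex or other differences between the trees underlie these probes was not tested.

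Other splits of the samples into groups of the same sizes were compared with the real split. For inner against outer stem 2 of 100 splits gave as many probes, the real 527 included. The highest other split gave 1817, with inner samples 1, 2 and 3 and outer samples 1 and 2 on one side, which points to a structure of the samples. That side holds every array of slide 1, which are also all the stem samples of 22 April and 27 May, so slide and season cannot be told apart in it. With slide as a fixed block, which takes the 13 January arrays out of the contrast, 1372 probes were called. The stem samples are paired, and the 16 splits that part all 5 pairs are too few for a share under 0.05 (real 527, highest other 0). Chance assignment of single samples can be excluded with 1 split as large, the real one, for male against female flowers (1 of 84, 2074 against at most 209). The same holds for fruit against female flowers (1 of 100, 4239 against 1219). It also holds for exchanged sexes in leaves (1 of 100, 913 against 1) and reassigned dates in the fruit season (1 of 100, 2883 against 4) and leaf season (1 of 100, 4200 against 2643). These splits and those of the tissues ignored slides and scan days, so they cannot exclude batch. With slide as a random block 94 probes were called for the flowers. As a fixed block it gave 195 for fruit against female flowers, 13 for the leaves of the sexes and 0 for both seasons (limma, 1095 in fruit and 1084 in leaves at an unadjusted p under 0.05). For the tissues the real counts, each with 1 of 100 splits as large, were 210 in leaves (highest other 0), 66 in inner stem (53), 165 in outer stem (0), 44 in female flowers (0), 341 in male flowers (18) and 49 in fruit (0). For the slopes of the sexes the real count was 0 (limma; 411 at an unadjusted p under 0.05), so that 100 of 100 splits gave at least as many by necessity (highest other 96) and nothing follows.

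The arrays of the fruit arms are matched by time, and exchanges within times make 8 splits, too few for a share under 0.05. Their highest others were 3807 for IAA (real 3169), 1751 for NPA (2294), 2421 for IAA plus NPA (3109), 2821 for ABA (3343) and 0 for IAA plus NPA against IAA (6). Of all 35 splits, which also exchange times, 2 gave as many for IAA (highest other 3807), 3 for NPA (2784), 2 for ABA (4805), and 1, the real one, for IAA plus NPA (2421) and for IAA plus NPA against IAA (1). The highest other splits for IAA, NPA and ABA kept the untreated arrays of 3, 6 and 12 h together, which are the arrays of slide 14 and scan day 7. With scan day as a fixed block 4 probes were called for IAA and 190 for IAA plus NPA, and the NPA and ABA contrasts could not be fitted. The arrays of the times are matched by arm, and exchanges within arms make 16 splits, also too few (3 h: real 3, highest other 0; 24 h: 5227 and 3075). Of splits that also exchange arms, 3 of 100 gave as many at 3 h (highest other 139) and 1 of 100 at 24 h (3649), and the 139 points to a structure of the arrays that was not traced. The leaf series allow 9 splits, too few for a share under 0.05, with 1 split as large each for heat at 3 h (32; highest other 0), heat at 24 h (4; 1) and light (1; 0).

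Single samples lay apart from the rest of their group in 7 of the 136 sets of a named probe and a group, and chance gives about 1 in 20 groups. The measure is the gap to the nearest sample divided by the range of the group. Outer stem replicate 5 (13 January) held 4 of the 7: Contig2278 at -2.65 against -6.84 to -6.09 (0.821), EuIPPI at 0.00 against 1.43 to 1.85 (0.773), EuTPL1 at -9.45 against -5.98 to -4.70 (0.732) and GAPDH 12321 at -1.12 against 1.81 to 2.94 (0.722). RT035_J12.b stood at 0.25 in outer stem replicate 1 (22 April) against -10.06 to -7.44 (0.746). ACC 7060 stood at 1.07 in inner stem replicate 4 (1 October) against 0.67 to 0.77 (0.754). RB049_D19.b stood at 0.39 in female flower replicate 6 (27 May) against 3.25 to 4.90 (0.633).

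Between the IAA plus NPA and IAA arms 6 probes differed by limma's test, among them RT036_K18.b (1.80), Contig1312 (1.15) and Contig4116 (-1.46). DXS 12602 was higher in every sample of the IAA and IAA plus NPA arms and lower in every sample of the ABA arm, by 0.92 and 0.72 between the mean differences, which was not tested. HMGS 10370 was lower in every sample of the NPA and IAA plus NPA arms and higher in every sample of the ABA arm, with -0.61 and -0.34 between the mean differences, which was not tested either.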

How the results depend on the processing

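The fits with slide or scan day as a fixed block, with scan day as a random block and without immature fruit replicate 12 were chosen only after the data were seen, and the other alternatives before. Of 422 counts of called probes under an alternative, 284 lay within 1.5 times the reported count and 138 did not. Of 3601 values of named probes, 2878 kept their direction and their side of the threshold, 675 kept the direction and lost the call, and 48 reversed. All 126 values named for inner against outer stem kept their call, as did 302 of 320 for fruit at 24 h, 300 of 313 for leaves against other tissues and 233 of 241 for outer stem. The cause was not tested for any count or value that moved unless one is given.

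The reported counts are 527 for inner against outer stem, 2074 for male against female flowers, 4239 for fruit against female flowers, 2883 for the fruit season, 913 for the leaves of the sexes and 4200 for the leaf season. For the fruit arms they are 3169 (IAA), 2294 (NPA), 3109 (IAA plus NPA), 3343 (ABA) and 6 (IAA plus NPA against IAA), and for fruit by time 3 (3 h) and 5227 (24 h). For leaves they are 32 (heat at 3 h), 4 (heat at 24 h), 0 (cold, limma, 1454 at an unadjusted p under 0.05) and 1 (light). For the tissues they are 210 (leaf), 66 (inner stem), 165 (outer stem), 44 (female flower), 341 (male flower) and 49 (fruit).

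With slide as a random block the counts were 1618 for the stem parts, 94 for the flowers, 922 for fruit against female flowers, 739 for the fruit season, 300 for IAA, 2 for NPA, 682 for IAA plus NPA, 361 for ABA, 0 for IAA plus NPA against IAA (limma, 698 at an unadjusted p under 0.05), 387 for fruit at 3 h, 3 for female flowers and 13 for fruit against other tissues. With slide as a fixed block they were 1372 for the stem parts, 195 for fruit against female flowers, 13 for the leaves of the sexes, 3 for IAA, 1 for IAA plus NPA, 1 for IAA plus NPA against IAA and 190 for fruit at 3 h. In the tissues this block gave 791 for leaf, 26 for inner stem, 88 for outer stem and 134 for male flower. It left 0 calls by limma for the fruit season (1095 at an unadjusted p under 0.05), the leaf season (1084), heat at 3 h (848) and 24 h (752), light (233), female flowers (1297) and fruit against other tissues (3673).

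With scan day as a fixed block the counts were 827 for the stem parts, 2040 for fruit against female flowers, 773 for the fruit season, 491 for the leaf season, 4 for IAA, 190 for IAA plus NPA, 133 for IAA plus NPA against IAA, 24 for fruit at 3 h, 917 for leaf, 4 for female flower, 210 for male flower and 12 for fruit against other tissues. With scan day as a random block they were 850 for the stem parts, 94 for the flowers, 2477 for fruit against female flowers, 947 for the fruit season, 19 for IAA, 1 for NPA, 207 for IAA plus NPA, 0 for ABA (limma, 911 at an unadjusted p under 0.05), 34 for IAA plus NPA against IAA, 11 for fruit at 3 h, 396 for leaf, 27 for female flower and 29 for fruit against other tissues. The contrasts of male against female flowers, NPA and ABA could not be fitted with slide or scan day as a fixed block, nor could cold with slide. For the stem parts both fixed blocks take out the 13 January arrays, each the only stem array on its slide and scan day. For the leaf series scan day adds nothing, because each series was scanned within a single day. Cold could not be fitted without the 15 °C series.

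Stem samples are paired by number and date, and with the replicate block 2110 probes were called between the stem parts, 526 of the 527 among them, and no named call changed. Flowers share only a number. There the same-numbered pairs correlated at r = 0.398, 0.0977 and -0.121 across probes, and the samples did not each correlate best with their own number. The replicate block gave 358 calls, but that fit holds only the numbers found in both sexes and leaves out the later female flowers. Fruit and female flowers correlated at -0.258 to 0.0731, and the replicate block gave 4239 calls, 3289 of them shared. That fit likewise leaves out the later fruit, whose numbers no female flower has. For flowers and fruit the block and the smaller set of samples therefore cannot be told apart.

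Signal over background limits the dim probes. Requiring every array to be well above background tests fewer probes and gave 331 for the stem parts, 36 for fruit at 3 h, 110 for heat at 3 h, 21 for heat at 24 h, 10 for cold, 10 for inner stem, 57 for outer stem, 13 for female flower and 22 for fruit against other tissues. Normexp correction, which compresses dim signals, gave 359 for the flowers, 324 for the leaves of the sexes, 2280 for the leaf season, 67 for fruit at 3 h, 62 for heat at 3 h, 8 for heat at 24 h, 2 for cold, 2 for light and 24 for female flower. Under normexp the gDNA probe turned from -1.33 to 0.28 between the flowers. Quantile normalization gave 14 for IAA plus NPA against IAA and 23 for fruit at 3 h.

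Fewer or other samples also moved counts. Without the 13 January arrays the stem parts gave 883, 477 of them shared, with only April female flowers the flowers gave 1359, and without the date block the leaves of the sexes gave 149. Without the 11 April pair 2 leaf slopes differed by sex. A quadratic leaf season gave 7484 probes, since it also counts curves. Relative to each arm's own 0 h array the counts were 1665 for IAA, 1874 for ABA and 167 for IAA plus NPA against IAA. That fit leaves out the error of the single 0 h arrays, so its counts and calls are no valid test. With only the compared arms in the fit they were 116 for IAA, 6 for NPA, 1371 for IAA plus NPA, 688 for ABA and 83 for IAA plus NPA against IAA. With only 0 h and the later time in the fit they were 0 for 3 h (limma, 2230 at an unadjusted p under 0.05) and 3099 for 24 h. Without the light term heat at 24 h gave 0 (limma, 1699 at an unadjusted p under 0.05).

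Replicates were left out 1 at a time only in inner stem, outer stem and male flowers, besides immature fruit replicate 12. This gave 363 to 766 for the stem parts and 1716 to 2325 for the flowers (male replicates). For the tissues, whichever of these arrays was left out, it gave 150 to 229 for leaf, 38 to 111 for inner stem, 122 to 218 for outer stem, 29 to 53 for female flower, 229 to 429 for male flower and 37 to 50 for fruit against other tissues. Without immature fruit replicate 12 the count was 5454 against female flowers and 3685 for the season. Leaving out 1 time gave 54 to 5219 for IAA, 11 to 4015 for NPA, 643 to 4760 for IAA plus NPA, 339 to 4870 for ABA and 0 to 20 for IAA plus NPA against IAA. Leaving out 1 arm gave 0 to 0 at 3 h and 4179 to 5340 at 24 h. Leaving out 1 leaf series gave 0 to 32 for heat at 3 h, 0 to 6 for heat at 24 h, 0 to 0 for cold and 0 to 1 for light. For these zeros limma left between 221 and 2071 probes at an unadjusted p under 0.05.

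Taking each array relative to its arm's own 0 h array reversed several named probes. For IAA these were EuAc3 (-0.54), EuTPL5 (0.0064), GGPPS 14500 (1.00), HMGR 13453 (0.21), MK (0.23), rRNA (0.25) and RB028_J02.b (2.65), and for NPA EuAc3 (-0.13) and RB030_C04.b (0.71). For IAA plus NPA they were DXS 12602 (-0.022), DXS 13333 (-0.082), EuAc3 (-0.64), EuTPL5 (0.11), GGPPS 14500 (0.54), HMGR 13453 (0.43), rRNA (0.46), Contig3451 (-0.89) and RB028_J02.b (2.87). For ABA they were DXS 12602 (0.054), DXS 12638 (-0.22), EuAc3 (-0.63), HMGR 13453 (0.14), rRNA (0.47) and RB030_C04.b (0.46). These values rest on a baseline of 1 array per arm.

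With slide as a fixed block ACC 7060 (0.089) and HMGR 8220 (-0.064) reversed between fruit and female flowers, EuAc1 (0.0052) and RB057_O23.b (-0.41) in the fruit season, and EuAc1 (0.025) and EuAc6 (0.17) in the leaf season. The same block reversed EuAc3 (-0.067) for IAA, and DXS 13333 (-0.069), EuAc3 (-0.40), EuTPL5 (0.084) and rRNA (0.14) for IAA plus NPA. In the tissues it reversed MPD in leaf (0.31) and GGPPS 10475 in outer stem (0.24). With scan day as a fixed block ACC 7060 (0.21) and EuAc4 (0.093) reversed between fruit and female flowers, EuAc6 (0.15) in the leaf season, EuAc3 (-0.031) for IAA, and EuAc3 (-0.25) and HMGR 13453 (0.14) for IAA plus NPA. With scan day as a random block ACC 7060 (0.066) reversed between fruit and female flowers. Without the April arrays EuHMGR (0.0039), HMGR 13453 (0.084) and rRNA (0.014) reversed in the leaf season.

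The median difference of all probes between male and female flowers was -0.19 in the main scaling, 0.04 after quantile normalization and 0.21 after normexp. In male flowers against other tissues it was -0.13, or 0.30 after normexp, and in leaves -0.17, or -0.05 after quantile normalization. Of the calls between the flowers 33.1% were higher in males, 51.5% after quantile normalization and 48.2% after normexp. In the fruit season 39.99% rose, 64.3% after quantile normalization, and in the leaf season 39.5%, against 54.0% and 53.2% after normexp. After quantile normalization 50.5% of the calls were higher for IAA (71.2% in the main scaling), 51.4% for NPA (71.0%), 49.6% for IAA plus NPA (70.9%) and 46.6% for ABA (73.7%). Median, mean and camera direction had the same sign for every list that passed camera. They differed in sign for lists that did not pass, such as the mevalonate list between the stem parts (median -0.10, mean 0.10) and the EuTPL list for NPA (0.03 and -0.11).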

Other observations

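The values below come from no test except the fit without immature fruit replicate 12, which was chosen only after the data were seen.

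RB035_A06.b, the probe at least 212-fold higher in male than in female flowers, was also measured in tissues that no sex comparison used. It lay well above background in 21 of 21 leaves of the heat, cold and light series and in 10 of 10 current-year stem samples, all labelled male. In immature fruit, labelled female, it was at -7.68 on 10 June, not above background, at -5.59 on 24 June, and between -5.33 and -2.99 from 8 July on, so that 11 of 12 fruit arrays were above background. It was not above background in the fruit wing, in the fruit without its wing, or in any of the 25 fruit arrays of 30 May.

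The single leaf buds correlated across probes most with female flowers among the 6 tissue means, at r = 0.936 for the male and 0.948 for the female bud. The fruit wing and the fruit without its wing correlated with the immature fruit mean at 0.937 and 0.938. Probes are not independent replicates, and these arrays have none.

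Immature fruit replicate 12 carries the same date, 28 October, as replicate 11. It had the lowest 75th percentile of signal (766) and the lowest share of probes above background (76.3%) of all arrays. It correlated across probes with the other fruit at r between 0.716 and 0.850, while replicates 10 and 11 correlated at 0.991. It lay on slide 13 and scan day 7, the other fruit on slides 5 to 8 and scan days 3 and 4. Without it 5454 probes were called between fruit and female flowers.

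The 3 male leaf arrays of 19 June correlated with each other at r between 0.979 and 0.986. No arrays were identical, and the closest pair, untreated fruit at 3 h and 6 h, correlated at 0.998.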
